A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

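RNA of Halobacterium salinarum NRC-1, an extremely halophilic archaeon, was measured on spotted two-colour arrays. Per the labels, the cells carried deletions of the ura3 and ark genes, and 50 mL cultures in 125 mL flasks were grown in rich medium to mid-log phase. High oxygen stands for shaking at 210 rpm and low oxygen for shaking at 100 rpm in a stoppered flask, and each was combined with light or with darkness. The 4 RNA extracts, 1 per condition, were each hybridised on 2 arrays against a standard RNA of mid-log NRC-1 cells taken at an OD600 of 0.5 to 0.6, with the dyes exchanged between the 2 arrays. RNA was prepared with a column kit, tested for DNA by PCR and inspected on a Bioanalyzer, per the labels' protocols.

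Per the file headers, the scanner files hold the median intensity of each spot and of its local background for Alexa 532 and Alexa 647, each on a high and a low scan, with no normalization recorded. A confidence score per spot is also given, per the file headers. On the high scans every spot with a lowered score held a pixel at the scanner's maximum of 65535, and no spot was left out for its score. The deposited value table holds log10 ratios whose processing is not given in the sources used here. Set against the scanner values of the same spots, the deposited log10 values followed the raw high-scan ratio of Alexa 532 over Alexa 647 on every array, with correlations across spots of 0.63 to 0.98. Their sign was not turned with the dye orientation, and their array medians lay between 0.042 and 0.128, so an array-wide shift of unknown origin remains. The value table numbers spots by their place on the slide and not by the scanner's spot number. Matching by spot number gave correlations of 0.14 to 0.25 only, so names were assigned through the place on the slide.

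Each array carried 10752 spots in 48 blocks of 14 by 16 spots, with 2688 probes of 4 spots each in 2 printed copies. Spot brightness correlated at 0.92 to 0.94 between the printed copies of a probe and at 0.08 to 0.17 between neighbouring probes. The platform annotation gave 1 symbol for 532 spots and several for 0, which named 133 genes, and the other 2555 probes are unnamed here. No probe was named ark.

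High-scan spot medians were background-corrected with normexp (offset 50) and normalized by loess within each array (span 0.3, 4 iterations) with limma 3.58.1 in R 4.3.3. A dye at 65535 on the high scan took its low-scan value, scaled by the median ratio of the scans over low-scan intensities of 1000 to 2000. This choice was made after the extent of saturation had been seen. The 4 spots of a probe were averaged, ratios were turned to own RNA over reference, and the 2 dye orientations of an extract were averaged. The extract is therefore the unit of the test, and nothing in the labels says how many cultures stand behind an extract. Conditions have no replicate extracts, so p-values measure no spread between replicates. A probe was called above background on an array when its own-RNA channel exceeded the local background in at least 3 of its 4 spots, a definition set after the files had been seen. It was met on all 8 arrays by 1104 probes and by 94 of the named genes.

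Oxygen (low minus high) and light (light minus dark) were fitted together with lmFit and eBayes over the 4 extracts. This leaves 1 residual degree of freedom per probe, which is the difference of the oxygen effects between light and dark. Standard errors and p-values of both effects take that difference as error. They are moderated by eBayes with a prior of 2.82 degrees of freedom drawn from all probes. Adjusted p-values are limma's after Benjamini-Hochberg adjustment over 2688 probes, with a threshold of 0.05. With 1 extract per condition, the difference of the oxygen effects between light and dark has no test. The ratio to the reference is given as mean and SD over the 4 extracts, and no test of it was planned or run. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Of 28 lists fixed before the data were examined, 8 had at least 3 named members. Another 10 lists were written once the gene names, but no values, were known.

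The genes named in the text followed a rule fixed before the data were examined. It takes the deleted genes. For each effect it takes the 10 largest changes per direction past the threshold, filled by size from genes whose 4 dye-matched array differences share the sign of the mean. For the oxygen by light difference it takes the 5 largest per direction with one sign in both dye orientations, and for the reference the 10 largest per direction with one sign on all 8 arrays. It also takes the 4 largest members of each list past its test, and of the purple membrane, gas vesicle, arginine fermentation and DMSO respiration lists whatever their test.

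The fit was tested on 20 simulated data sets per effect with 2688 probes, 200 of them changed. For oxygen it called 53.4% of probes changed by 1 on the log2 scale (16% to 94% between data sets). Of those changed by 2 it called 97.4%. For light these shares were 59.6% (12% to 91%) and 97.8%. Smaller changes were not simulated, and no named gene changed by more than 1 for either effect. The share called at the sizes reported below is therefore not known. The simulated noise was independent between probes. Array noise was added to extract noise that already held it, so simulated extract means were noisier than the fit to the data implies. The shares called may therefore be too low. Of the calls, 8.31% were false for oxygen and 8.41% for light, above the 5% aimed at, and the highest share in one data set was 27.1%. Alternatives covered the background correction, the normalization, the averaging of spots, the scan, filters on dim probes, the variance model, the treatment of arrays as observations, the deposited values and the omission of each array. An extract with 1 array left out keeps only 1 dye orientation, so ranges over arrays left out also hold its dye bias. The precision of all values is limited by the number of arrays.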

Results

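Transcript levels were compared among 4 RNA extracts of a Halobacterium salinarum strain lacking ura3 and ark, grown at high or low oxygen in light or in darkness. Each of the 4 groups had 1 RNA extract on 2 arrays, replicate 1 with its own RNA in Alexa 532 and replicate 2 with it in Alexa 647. Median high-scan intensities lay between 1575 and 2562 for Alexa 532 and between 2292 and 4750 for Alexa 647. Between 49.6% and 86.0% of the probes were above background in the channel of the cultures' own RNA. The direction of every ratio rests on the dyes in the labels. Turned accordingly, the ratios to the reference from the 2 dye orientations correlated at -0.06 across the 2688 probes, which are not independent replicates. Between the dye orientations the oxygen effect correlated at 0.22 (0.30 over probes above background on all 8 arrays) and the light effect at -0.20 (-0.08). The light effect thus did not repeat between the dye orientations, and these correlations do not settle whether the labelled dyes are right. Over probes above background on all 8 arrays, arrays of different extracts with the same dye orientation correlated at 0.40 to 0.76. The 2 arrays of an extract correlated at -0.07 to 0.26, so the dye orientation outweighed the extract in these ratios.

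The deleted gene ura3 is represented by pyrF, which encodes orotidine 5'-phosphate decarboxylase of uridine synthesis. The pyrF probe was above background with own RNA on 1 of 8 arrays. On the other 7 arrays its own-RNA signal was 0.612 to 1.07 times the local background. The exception was the Alexa 532 array of low oxygen in dark, where pyrF stood at 1.89 times background in 4 of 4 spots, while the Alexa 647 array of the same extract gave 0.798. The reference RNA, of cells with the gene, gave pyrF signals of only 0.730 to 1.03 times background and was above background, by the same definition, on 3 of 8 arrays, on which own RNA was not. The probe is dim with either RNA and is a weak check of the deletion. The second deleted gene, ark, was not analysed here, because no probe carried its name.

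**Figure D1:**
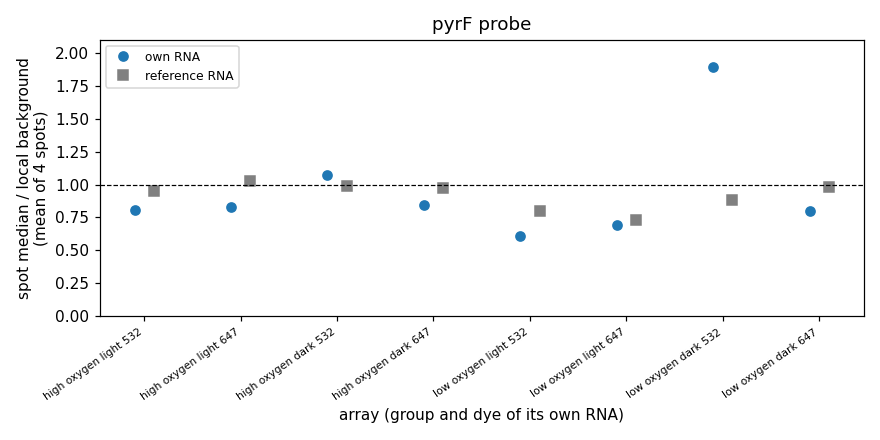
Signal of the pyrF probe over its local background (mean of 4 spots, linear axis) on each array, with own RNA as circles and reference RNA as squares; the dashed line marks a signal equal to background. Own RNA lies between 0.612 and 1.07 on 7 arrays and at 1.89 on the Alexa 532 array of low oxygen in dark.

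The first comparison asked how transcript levels differed between low and high oxygen. No named gene passed the test. Of the named genes above background on all 8 arrays, glyA, encoding serine hydroxymethyltransferase, had the highest value (low minus high oxygen), at 0.34 ± 0.13 (log2, SE, 2 extracts per oxygen level). It was followed by phoU, a regulator of phosphate uptake, at 0.31 ± 0.14, and by panB at 0.31 ± 0.13. The lowest were gdhA1, a glutamate dehydrogenase, at -0.41 ± 0.15, tpiA, the glycolytic triosephosphate isomerase, at -0.35 ± 0.13, and surE at -0.24 ± 0.14. These genes were taken from those with the same sign in their 4 dye-matched array differences, as the rule requires. That agreement is therefore no further evidence. With 1 array left out, gdhA1 ran from -0.58 to -0.24, tpiA from -0.44 to -0.25, glyA from 0.24 to 0.45 and phoU from 0.16 to 0.46. With print-tip loess, which normalizes each block of spots by itself, phoU was at 0.02. Over the alternatives that left out no array, surE ran from -0.45 to -0.05.

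The other genes above background that the rule selected were dnaK, cheY and thiC, from 0.10 to 0.15, and pyrI, thrS, citZ and pheA, from -0.24 to -0.16. With 1 array left out, thiC ran from 0.0033 to 0.19, dnaK from 0.06 to 0.24 and thrS from -0.40 to -0.05, and on the high scan alone pyrI was at -0.0022. Over the other alternatives cheY ran from -0.00024 to 0.22, dnaK from 0.04 to 0.16 and thiC from 0.02 to 0.14. The genes purM (-0.25) and radB (-0.33) were above background on 7 and 5 arrays, and glyS and mamA on 1 array each. With 1 array left out, purM ran from -0.42 to -0.08. The gene hutI, of histidine degradation, was above background on 0 arrays so no change is read from its values. With limma, 0 of 2688 probes passed an adjusted p of 0.05, the smallest adjusted p was 0.89, and 80 probes had an unadjusted p under 0.05 where 134.4 would be expected by chance, a count that ran from 19 to 249 with 1 array left out. With a variance trend and robust estimation, 13 probes passed, among them gdhA1 (adjusted p = 0.000811, limma), glyA (0.00271) and phoU (0.0187). From the low scans alone tpiA was at 0.03 and purM at 0.02, opposite in sign. Among named genes, 24 of 133 had one sign in all 4 differences (18.0%), against 14.2% of all probes and 12.5% for independent signs.

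None of the 8 gene lists fixed beforehand passed for oxygen with camera, an estimated correlation or fry, and in each of them 0 members passed, adjusted over all probes and adjusted over the list alone. All 5 photoreceptor and transducer genes (hop, sop1, sop2, htr1 and htr2) were below 0, with a median of -0.07 (camera adjusted p = 0.838). In purine and pyrimidine synthesis, 7 of 9 members were below 0, with a median of -0.11 (camera adjusted p = 0.838). The members above 0 were the deleted gene pyrF and purB, each above background on 1 array. The 6 members above background on all 8 arrays (purD, purE, purF, purL, pyrB and pyrI) were all below 0. With the test restricted to such probes, a choice made after seeing the data, camera gave this list an adjusted p of 0.0406. That call was lost with an estimated correlation (adjusted p = 0.735 with an estimated correlation) and with fry (adjusted p = 0.522). Of the 6 cobalamin and heme genes, 5 were below 0, with a median of -0.05 (camera adjusted p = 0.923). The tricarboxylic acid cycle genes were split 3 and 3, with a median of -0.01 (camera adjusted p = 0.923). The chemotaxis genes cheA, cheR and cheY were above 0 and cheB below, with a median of 0.07 (camera adjusted p = 0.838). The 4 members of the proteasome and protease list (psmA, psmB, pan1 and panB) were split 2 and 2 (camera adjusted p = 0.838); the one with the largest value, panB, was caught by the search pattern for proteasome-activating ATPases and is known as a pantothenate synthesis gene. The 7 taxis transducers (3 above 0, mean -0.01, camera direction up) and the 4 DNA repair genes (2 above 0) each gave a camera adjusted p of 0.923. The arginine fermentation genes arcA and arcC were at -0.03 ± 0.14 and -0.05 ± 0.13. The purple membrane regulator bat was above background on 0 arrays, and no gas vesicle or DMSO respiration gene was among the named probes.

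**Figure D2:**
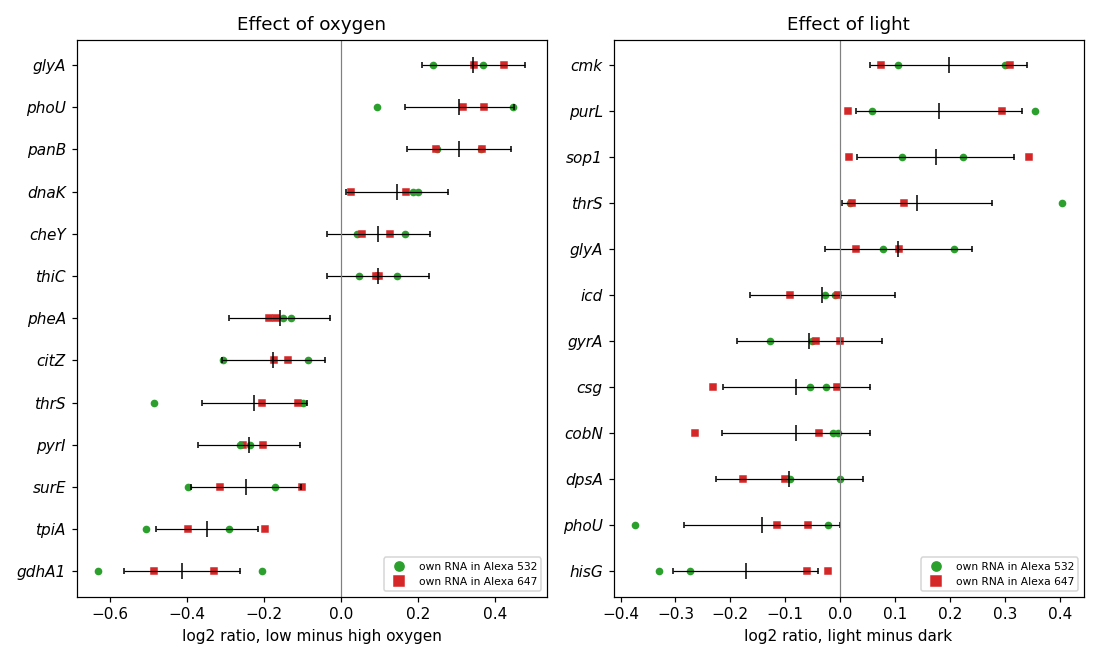
Genes selected by the naming rule and above background on all 8 arrays, with the oxygen effect at left and the light effect at right (log2 ratio). Circles and squares are the 4 dye-matched array differences, and the bar and whiskers are the mean and its standard error from limma. At left gdhA1 lies lowest at -0.41 and glyA highest at 0.34.

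The second comparison asked how transcript levels differed between light and dark. No named gene passed the test. Among genes above background on all 8 arrays with one sign in the 4 dye-matched array differences, cmk, a cytidylate kinase, had the highest value (light minus dark) at 0.20 ± 0.14 (log2, SE, 2 extracts per light level), followed by purL of purine synthesis at 0.18 ± 0.15. The gene sop1, encoding sensory rhodopsin I, a light receptor of phototaxis, was at 0.17 ± 0.14. The lowest were hisG of histidine synthesis at -0.17 ± 0.13 and phoU at -0.14 ± 0.14. With 1 array left out, sop1 ran from 0.03 to 0.31 and hisG from -0.26 to -0.09. Over the other alternatives cmk ran from 0.05 to 0.25, sop1 from 0.02 to 0.38 and hisG from -0.49 to -0.05, so the order of these genes depends on the setting. The probe of phoU was printed in the first row of blocks, where values were lower in light as a whole (median -0.20), and with print-tip loess phoU was at -0.03.

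The genes thrS and glyA (0.14 and 0.11) and dpsA, cobN, csg, gyrA and icd (-0.09 to -0.03) completed the selected genes above background on all 8 arrays. The gyrA probe lay in the first row of blocks too, and 3 csg spots on 1 array were saturated on both scans. The largest value past the selection rule, -0.44 ± 0.13 for the glycerol kinase gene glpK, came from a probe above background on 5 of 8 arrays and printed in the same first row of blocks. With 1 array left out glpK ran from -0.65 to -0.23, and over the other alternatives from -0.44 to -0.14. With limma, 0 of 2688 probes passed, the smallest adjusted p was 0.635, and 205 probes had an unadjusted p under 0.05 where 134.4 would be expected by chance, a count that ran from 76 to 235 with 1 array left out. Of the 134 among them that were lower in light, 94 lay in the first row of blocks, which holds 448 probes; elsewhere 105 of 2240 probes had an unadjusted p under 0.05, 40 of them lower. With each block normalized by its own loess, 132 probes had an unadjusted p under 0.05. The values of thrS, glyA, phoU, dpsA and cobN changed sign when single arrays were left out, while csg ran from -0.15 to -0.01 and icd from -0.05 to -0.01. Among named genes, 19 of 133 had one sign in all 4 differences (14.3%), against 10.8% of all probes and 12.5% for independent signs.

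None of the 8 lists passed for light with camera, an estimated correlation or fry, and every camera adjusted p was 0.789. No member passed, adjusted over all probes or adjusted over the list alone. The 4 members of the proteasome and protease list, panB included, were all above 0, with a median of 0.03. Of the 7 taxis transducers, 6 were below 0, with a median of -0.09. That median is the value of htr8, whose probe was printed in the first row of blocks. Only 4 of the 7 were above background on all 8 arrays. Tricarboxylic acid cycle (median 0.03), chemotaxis (0.02) and cobalamin and heme genes (0.01) had members on both sides. So had photoreceptors (median -0.01), DNA repair (-0.02) and purine and pyrimidine genes (-0.0038), whose camera direction was up although their medians were below 0. The genes arcA and arcC were at -0.06 ± 0.14 and -0.02 ± 0.13.

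The oxygen effect was also set side by side in light and in dark, with values only. The gene folP, of folate synthesis, had the largest difference among genes above background on all 8 arrays, at -1.04, with -1.56 from the Alexa 532 and -0.53 from the Alexa 647 arrays, followed by cca, a tRNA nucleotidyltransferase gene, at -0.64, with -1.22 from the Alexa 532 arrays and -0.05 from the Alexa 647 arrays. The probe of folP was printed in the first row of blocks. On the positive side htr7 (0.83), uvrA (0.64), aroC (0.48), dcd (0.47) and radB (0.40) led, all from probes below background on at least 1 array, as were gatC, trpC and mutL on the negative side. Between the Alexa 532 and the Alexa 647 arrays dcd differed from 0.89 to 0.06 and aroC from 0.77 to 0.18. Against the spread between dye orientations alone, which is technical, limma called 0 probes for this difference (smallest adjusted p 0.408, 110 with an unadjusted p under 0.05). Across probes the oxygen effects in light and in dark correlated at -0.03, and from -0.24 to 0.25 with 1 array left out.

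Set against the reference, 12 of 133 named genes and 141 of 2688 probes had one sign on all 8 arrays, which share the reference RNA and are not independent. Independent signs would give 1.04 named genes and 21 probes, a comparison that the shared reference and the dye bias limit. Arrays of the same dye orientation correlated at 0.40 to 0.76 over probes above background on all 8 arrays, so their signs go together. Higher counts than for independent signs are therefore no evidence by themselves of a difference from the reference. Of these 12 genes, argH, encoding argininosuccinate lyase of arginine synthesis, was at 0.42 ± 0.04 (log2, SD, n = 4 extracts). The arginine fermentation genes arcC and arcA were at 0.25 ± 0.04 and 0.24 ± 0.06. The gene serB of serine synthesis was at 0.15 ± 0.05, and csg, encoding the cell surface glycoprotein, at 0.10 ± 0.05; 3 of the csg spots on 1 array were saturated on the low scan too. Below 0 were the ribosomal protein gene rpmC at -0.28 ± 0.10, hisI and carA at -0.14, cbiG at -0.12 and gyrA at -0.09. So were thiL at -0.27 ± 0.11 and lysS at -0.23 ± 0.08, whose own-RNA signal was above background on 7 of 8 arrays. The probes of serB, cbiG and gyrA lay in the first row of blocks, where the upper printed copy had own-over-reference medians of 0.65 and 0.63 on the Alexa 532 arrays of high and low oxygen in dark. Strain, culture and growth conditions differ between the extracts and the reference. No test of these ratios was planned or run, and their direction rests on the labelled dyes.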

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

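Tests of the explanations below were written before their values were seen, except those on the partner array of the low oxygen dark extract and on the correlation of the oxygen effects.

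For 8 genes named in the text the oxygen effect had one sign on both dye orientations in light and the opposite sign on both in dark, and the difference was not tested against replicate error. The difference (light minus dark, log2) was -1.04 for folP and -0.54 for the deleted gene pyrF, which was above background on 1 array. In dark, the oxygen effect of pyrF was 0.98 from the Alexa 532 arrays and 0.02 from the Alexa 647 arrays. The difference was 0.64 for uvrA and 0.20 for orc7, above background on 5 and 4 arrays. For sop1 it was 0.22, for cheB 0.20, for eno -0.20 and for arcA 0.14. Among all 133 named genes 18 had such opposite signs, where independent signs would give 16.6.

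Probes printed in the first row of blocks had lower values in light, with a median of -0.20 over 448 probes against 0.01 elsewhere. A response of these genes to light is argued against, since the median was -0.50 in the upper printed copy but 0.063 in the lower copy of the same probes. The gap between the copies was 0.57, as a dependence on slide position needs. The median was -0.025 from the Alexa 647 arrays alone, as an origin in the Alexa 532 arrays needs. These explanations may act together, since in the upper copy the Alexa 532 arrays of high and low oxygen in dark had own-RNA medians of 0.65 and 0.63.

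The Alexa 532 array of low oxygen in dark, which also gave the pyrF signal, had ratios with an SD of 0.80, against 0.27 to 0.46 on the others. Over probes above background on all 8 arrays its SD was 1.29 times the highest of the other 7 arrays. This is consistent with extra Alexa 532 signal on dim probes. Expression of the low oxygen dark extract called for a correlation of 0.3 or more between the deviations of this array and those of its partner array. The correlation was 0.0906, well below 0.3. It lay within the standard error of 0.03 from 0.1, the bound under which this explanation was to be dropped, so it was not dropped. This standard error treats probes as independent and covers no spread between arrays.

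The oxygen effects in light and in dark correlated at -0.03 across probes, from -0.24 to 0.25 with 1 array left out, with a jackknife standard error of 0.487. An extract left with 1 array keeps its dye bias, so this spread is not that of extracts alone. Measurement noise and a response that depends on light cannot be told apart, from the correlations of the dye orientations over probes above background. Noise alone called for values under 0.2 in both effects, and its absence for 0.5 or more in both, but they were 0.47 in light and 0.14 in dark. A response that depends on light called for 0.5 or more for their difference, and its absence for under 0.2. The correlation was 0.203, well below 0.5 and within the standard error of 0.03 from the bound of 0.2. That standard error treats probes as independent and covers no spread between arrays or extracts. Over all 2688 probes, on which the -0.03 rests, the dye orientations correlated at 0.07 in light, -0.08 in dark and -0.21 for the difference. These values meet the bound for noise and miss that for a response that depends on light. Only 1104 of these probes were above background on every array, and over those the oxygen effects in light and in dark correlated at 0.08.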

How the results depend on the processing

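The settings with the high or the low scan alone and with only probes above background on all 8 arrays were chosen after the data were seen. The cause of a change was not tested unless stated.

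With limma, 0 probes passed for light under the alternatives kept (normexp on the low scan, discarded below, had given calls). For oxygen 13 passed with trend and robust eBayes and 1, the unnamed probe spots_4845, among probes above background on all 8 arrays, where the purine and pyrimidine list passed camera too (adjusted p = 0.0406, and adjusted p = 0.735 with an estimated correlation). The other alternatives kept gave 0. The adjusted p (limma) of gdhA1 was 0.000811 with trend and robust eBayes and ran from 0.340 to 0.998 under the other alternatives, none of which called gdhA1, glyA or phoU.

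Unadjusted p under 0.05 for light was met by 65 of 1337 probes with plain subtraction and, of 2688 probes, by 132 with print-tip loess, 343 with deposited values, 108 with the 8 arrays as observations, and by 35 of 1104 probes above background. For oxygen it was met by 49 of 2016 probes without the dimmest 25% and, of 2688 probes, by 142 with trend and robust eBayes and 203 on the low scan. With single arrays left out these counts ran from 76 to 235 for light and from 19 to 249 for oxygen, with 249 without replicate 1 and 19 without replicate 2 of low oxygen in dark. For oxygen the omission of either high oxygen dark array (31 and 127), either high oxygen light array (183 and 47) or replicate 1 of low oxygen in light (183) also moved it by more than the tolerance set for a count. For light that held for replicate 1 of high oxygen in dark (118), replicate 2 of low oxygen in dark (76) and replicate 1 of low oxygen in light (98).

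The correlation of the dye orientations in the ratio to the reference went to -0.533 with median centring, 0.207 without the dimmest 25% of probes and -0.808 with deposited values.

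Opposite oxygen values came from plain subtraction for purM (0.12), print-tip loess for cheY (-0.00024), and the low scan for glyS (-0.069), hutI (0.00021, from a probe above background on 0 arrays), tpiA (0.031) and purM (0.023). Opposite light values came from plain subtraction for thiL (-0.33) and print-tip loess for gyrA (0.045). Deposited values gave radB -0.050, mamA -0.061, thiL -0.068, phoU 0.025, cobN 0.00043, csg 0.047, gyrA 0.039 and icd 0.060. The low scan gave mamA -0.00093, menD -0.024, orc7 0.16, gyrA 0.018 and icd 0.0074. With single arrays left out, light values ran from -0.033 to 0.31 for thrS, -0.0013 to 0.21 for glyA, -0.29 to 0.0095 for phoU, -0.22 to 0.030 for dpsA and -0.22 to 0.060 for cobN.

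Normexp on the low scan failed numerically on 3 arrays; its 9 oxygen and 14 light calls were discarded and the low scan was used without background correction. Aquantile moves no ratio, so it tests nothing here. Slide and scan blocks were not run, since no slide or scan date was used here. Dim probes limit all of this, as only 1104 of 2688 were above background on every array.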

Other observations

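The gene lists here were written once the gene names were known. None of the 10 passed camera, with adjusted p from 0.776 to 0.843 for oxygen and from 0.820 to 0.953 for light. The 12 aminoacyl-tRNA synthetase genes were split 6 and 6 for oxygen, with pheS at 0.27 ± 0.18 and thrS at -0.22 ± 0.14 (log2, SE; camera adjusted p = 0.776). Of the 3 lower glycolysis genes, tpiA was at -0.35, eno at -0.03 and ppsA at 0.05 (camera adjusted p = 0.776). All 3 histidine use genes lay below background on at least 7 of 8 arrays.

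Over probes above background on all 8 arrays, Alexa 647 arrays of different extracts correlated at 0.58 to 0.76 with each other, Alexa 532 arrays at 0.40 to 0.56 and the 2 arrays of an extract at -0.07 to 0.26. Over all probes the Alexa 647 arrays of different extracts correlated at 0.24 to 0.67 and the 2 arrays of an extract at -0.13 to -0.02. Only the range of the Alexa 532 arrays overlapped that of the 2 arrays of an extract. The Alexa 532 arrays of low oxygen in light and in dark correlated at -0.05.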
